A study of Bos taurus and Theileria annulata
Bos taurus with 18 samples.

How the data were processed

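RNA from the BL20 and TBL20 cell lines was measured on 18 custom single-colour NimbleGen arrays (Cy3), 3 for each of 6 groups, with the groups taken from the labels. The deposited scanner values are intensity, the brightness of each probe spot as whole numbers up to 65535, extracted by NimbleScan 2.4.31 per the file headers and not background-subtracted. The table with a single value per sequence is also intensity on a linear scale, which the authors made by RMA (background correction, normalisation between arrays and summary of the probes of a sequence, version not given) per the submitters' processing notes, with both species together. The scanner values were analysed, and the authors' values were used as an alternative. Their log2 values correlated at 0.983 to 0.993 with those made here.

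Each array held 343790 spots used here, 306228 for bovine and 37562 for parasite sequences, with 5 probes for 34344 of 34426 sequences and 2 copies of each probe. Bovine probes were processed apart from parasite probes, since the parasite probes have targets in TBL20 alone. Their intensity was background-corrected with normexp (offset 50), quantile-normalised across the 18 arrays, put on the log2 scale, averaged over the 2 copies and summarised per sequence by median polish (10 iterations). The offset makes the folds of dim genes smaller than they would be without it. The background threshold, log2 6.94, was the 95th percentile of the parasite sequences on the 9 BL20 arrays. The base composition of the parasite probes was not compared with that of the bovine probes, so the threshold is a rough guide for bovine sequences. Of the bovine sequences, 27309 above it on at least 3 arrays were tested and 3347 were not. Parasite sequences were corrected and normalised among themselves on the 9 TBL20 arrays, and 3489 above their level on BL20 arrays were tested. At most 0.026% of the spots of an array were at the scanner limit.

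Bovine sequences were named by their RefSeq accession in a table of bovine genes (ARS-UCD2.0) that holds names without positions, so no coordinates are given. Of 9647 accessions of curated transcripts (NM), 9267 had a symbol, and of 16585 predicted transcripts (XM or XR) 0 had one, so a gene known on the array only by a predicted transcript or an EST (4424 sequences) has no name here. Counts cover all tested sequences, and named genes and gene lists cover the 8578 with a symbol. Where several sequences shared a symbol (40 of 8529 symbols), the brightest over all arrays stood for it in lists.

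Differences were tested with limma 3.58.1 in R 4.3.3, with the packages data.table (version 1.17.8) and matrixStats (version 1.5.0). All 18 arrays entered 1 model of 6 groups (12 residual and 6.44 prior degrees of freedom), with empirical Bayes moderation and Benjamini-Hochberg adjusted p under 0.05 per comparison. The 11 bovine comparisons were the lines against each other at each of 3 times, each time after LPS against the control of its line, 18 h against 4 h in each line, and the interaction at 4 h and 18 h (response of TBL20 minus response of BL20). Standard errors are those of the model. Parasite sequences were compared in a model of the 9 TBL20 arrays. For 30 gene lists, the members past the test were counted, with p adjusted over all genes and over the list alone, and the shift of the list was tested with camera (preset correlation 0.01). Correlations of log2 changes across genes were set beside 20 simulations of unchanged groups that share the same arrays.

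The comparisons, lists and naming rule were chosen before the data were examined. The rule named, for 6 of the bovine comparisons, up to 6 genes with the largest rise and 6 with the largest fall among those past the test, above background on every array of the brighter group and without overlap between the replicates. It also named up to 4 members of each described list, a fixed set of genes whatever their values, and up to 2 parasite genes in each direction. Some genes that the rule names are not reported here. The test was tried on simulated data. The changed sequences were drawn from brighter sequences alone, so the shares called and the estimates do not cover dim ones. Of 50 sequences changed by 0.5 on the log2 scale, 43 were called (86%), with a median estimate of 0.46, and all 50 at each of 1, 2 and 3, with median estimates of 0.91, 1.89 and 2.80. Of 24996 unchanged sequences 8 were called. Of 20 simulated lists the 1 shifted by 0.5 was called and 0 others. Their members were drawn at random and varied independently, so this does not test the preset correlation for the real lists.

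The alternatives were all probes of both species together, no background correction, offset 0, median scaling, cyclic loess, mean of probes, no filter, a filter on all 18 arrays, the authors' values, fits to the groups compared, the replicate number or the scan batch as a block, 1 copy of the probes, array weights, a trend in the prior, stricter thresholds, other list tests and leaving out each array in turn. Analyses within a scan batch, without arrays of high background, and with scan batch as a block for the parasite, were chosen after seeing the data. The scan batch was read from the file headers. The second batch held TBL20 LPS 4 h 2 and TBL20 LPS 18 h 1 and 3. Whether replicate numbers pair samples across groups was checked by correlating deviations from group means. In 2 of 15 pairs of groups, BL20 control with BL20 LPS 18 h and BL20 LPS 4 h with BL20 LPS 18 h, every same-number correlation exceeded 0.1, over a range of -0.47 to 0.67 for same numbers and -0.60 to 0.59 for others, and the model took no pairing. No pair of arrays was identical. The mismatch column was 0 throughout and not used here, and the position of spots on the array was not analysed here.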

Results

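Gene expression was measured in cultures of a pair of related bovine cell lines, with 1 single-colour oligonucleotide array for each of 18 RNA samples. BL20 is an uninfected bovine lymphosarcoma line. TBL20 is the same line infected with Theileria annulata, a tick-borne parasite of cattle that lives in the cytoplasm of leukocytes and keeps them dividing. Cells of each line were sampled without lipopolysaccharide (LPS, a cell wall component of Gram-negative bacteria) and 4 h and 18 h after LPS was added at 1 µg per ml, which gave 6 groups of 3 arrays. Each array carried probes for 30656 bovine and 3770 parasite sequences. The control cultures have no time point after a mock treatment, so a change after LPS includes any effect of the fresh medium given before LPS and of time in culture. The labels do not state that replicates were separate cultures, so p-values measure only the spread between these samples.

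The median scanner intensity of the bovine probes ranged from 311 to 415 across the 18 arrays, and the correlation between replicates of a group was 0.989 to 0.998 in log2 intensity. The number of arrays limits the precision, with a median standard error of 0.114 in log2 for a comparison of 2 groups. Parasite sequences gave the background: 1.51% to 4.22% of them exceeded the background threshold in the BL20 groups, from which the threshold was set, against 81.9% to 85.6% in the TBL20 groups. Of the bovine sequences, 27309 exceeded the threshold on at least 3 arrays and were tested, and 8578 of them had a gene symbol. The first principal component held 60.9% of the variance and separated the lines, and the second held 13.3% and separated the BL20 control arrays from the BL20 arrays after LPS. No named sequence for TNFAIP3, IRF1, IRF4 or PAX5 was found on the array. CD14 was above the threshold on at most 1 array of any group and was not detected, and IL6 lay close to the threshold in each group, so their values do not measure these genes. Differences of CXCL10, MX2, MMP13 and NKG7 against the BL20 control, and of CYSLTR1 and BOLA-DYA against the TBL20 control, rest on a control group with 1 array above the threshold and are imprecise in size. IL10 was above the threshold on 1 BL20 array at 4 h and 1 at 18 h after LPS, so its changes in BL20 are imprecise as well. Other control means also lay close to the threshold of 6.94. Examples are SLAMF1 (7.02), PPP1R14C (7.11), RAG2 (7.18) and BLK (7.24) in TBL20 and XCL1 (7.16) in BL20. Folds against such controls are imprecise in size too.

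The comparison of TBL20 with BL20 without LPS asks what distinguishes the infected line. Matrix metalloproteinases were among the genes with the largest differences: MMP9, a gelatinase, was 201-fold higher in TBL20 (log2 difference 7.65 ± 0.10, SE, n = 3 arrays per group), and MMP13, a collagenase, was 39.8-fold higher (5.32 ± 0.13). XCL1, a lymphocyte chemokine, was 103-fold higher (6.69 ± 0.12), and ANXA1, which encodes annexin A1, was 55.1-fold higher (5.78 ± 0.11). SH3BGRL2 was higher by 4.97 ± 0.13. PPP1R14C, an inhibitor of protein phosphatase 1, was 48.2-fold lower in TBL20 (log2 difference -5.59 ± 0.13), and the leukotriene receptor gene CYSLTR1 was 28.2-fold lower (-4.82 ± 0.13). A2M (-4.72 ± 0.17), the lymphocyte receptor gene SLAMF1 (-4.66 ± 0.17) and the B cell kinase gene BLK (-4.60 ± 0.14) were also lower. C1QTNF1 was above background on no TBL20 control array and was at least 21.5-fold lower there (adjusted p = 1.7e-15). The limma adjusted p of these 11 genes lay between 1.4e-20 and 3.0e-14.

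B cell markers were lower in TBL20. Of 16 measured, 12 were lower and 0 higher (12 and 0 adjusted over the list alone), among them RAG2 (-3.30), JCHAIN (-3.27), MS4A1 (-2.79) and CD79A (-2.48). The list median was -1.01 (camera adjusted p = 4.1e-11), and under median scaling it was -0.53 (camera adjusted p = 1.5e-13). MHC class II presentation genes had 7 of 10 lower and 0 higher (8 and 0 adjusted over the list alone), with BOLA-DOB at -2.77 and BOLA-DMB at -1.29. Their camera adjusted p was 0.00036, and the adjusted p = 0.0548 with an estimated correlation. The near-identical copies of MHC and OAS genes make the identity of those named here uncertain.

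Interferon-stimulated genes were higher in TBL20 without LPS. Of 29 measured, 20 were higher and 2 lower (21 and 2 adjusted over the list alone), with MX2 (3.82), ISG15 (3.52), RTP4 (3.17) and MX1 (2.98) as examples. The list's camera adjusted p was 1.3e-07, and the adjusted p = 0.0548 with an estimated correlation. The interferon regulator IRF7 (2.14) was also higher. NF-kB pathway and target genes had 12 of 24 higher and 3 lower (13 and 3 adjusted over the list alone), with ICAM1 at 4.36, IER3 at 3.02 and NFKB2 at 2.89. The apoptosis inhibitor BCL2A1, above background on no BL20 control array, was at least 6.19-fold higher. Camera gave that list an adjusted p of 0.0032, and the adjusted p = 0.303 with an estimated correlation. AP-1 and immediate early genes had 8 of 15 higher and 0 lower (8 and 0 adjusted over the list alone), among them JUND (2.76), FOS (1.94) and JUN (1.44). Their camera adjusted p was 0.0417, and the adjusted p = 0.303 with an estimated correlation. The list of matrix metalloproteinases, inhibitors and invasion genes had 9 of 17 higher and 1 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.0417, adjusted p = 0.336 with an estimated correlation). Camera calls for the AP-1 and invasion lists were lost under several other settings, among them the mean of probes (adjusted p = 0.0699 and 0.0651).

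Hypoxia-inducible genes had 11 of 19 higher in TBL20 and 3 lower (12 and 4 adjusted over the list alone), with the glucose transporter gene SLC2A1 at 2.69 and NDRG1 at 2.65 (camera adjusted p = 0.0081, adjusted p = 0.207 with an estimated correlation). Cholesterol biosynthesis genes had 16 of 21 higher and 1 lower (17 and 1 adjusted over the list alone), with LSS at 1.31 and SREBF1 at 1.08 (camera adjusted p = 0.00073, adjusted p = 0.191 with an estimated correlation). Of 19 LPS recognition genes, 3 were higher and 5 lower (3 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.0794). It passed downward with both species normalised together (adjusted p = 0.0276) and with the authors' values (0.0426). It also passed downward with fry (adjusted p = 5.7e-06), which tests a list against no change, whereas camera tests it against the other genes. TLR4, the receptor of LPS, had a log2 difference of -4.17 ± 0.10 (adjusted p = 9.6e-17). LY96 (-0.70, adjusted p = 0.0034) and TNF (-0.81) were lower, and both lost their call with arrays scaled to a common median (adjusted p = 0.117 and 0.0689). MYC (-0.40, adjusted p = 0.0271) and NFKBIA (-0.44, adjusted p = 0.0143) passed on all 18 arrays but not under median scaling. MYC did not pass without BL20 control 2 (adjusted p = 0.0815), BL20 control 3 (0.0913), TBL20 control 2 (0.0763) or TBL20 control 3 (0.135). NFKBIA did not pass without BL20 control 3 (0.0534), TBL20 control 1 (0.0515) or TBL20 control 2 (0.0512). IL6 (-0.02) and IL10 (-0.15) did not pass, though IL10 passed with both species normalised together and with the authors' values (adjusted p = 0.0053 to 0.0156).

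Markers of other cell types gave no list call by camera in this comparison. T cell and NK cell markers had 8 of 22 higher, such as IL2RA (3.16), NKG7 (3.23) and CD28 (at least 10.9-fold higher, above background on no BL20 control array), and 4 lower, such as LCK (-4.27), and 8 and 4 adjusted over the list alone. Their median was -0.06, their mean 0.44 and the test pointed upward (camera adjusted p = 0.541). Monocyte, macrophage and dendritic cell markers had 6 of 26 higher, among them CYBB (1.39), and 6 lower, among them FCGR1A (-2.80), and 6 and 6 adjusted over the list alone. Their median was 0.01, their mean -0.03 and the test pointed downward (adjusted p = 0.715). Of 13 fibroblast, endothelial and epithelial markers 1 was higher, ACTA2 (2.70), and 0 were lower (1 and 0 adjusted over the list alone). Their median was -0.03, their mean 0.20 and the test pointed downward (adjusted p = 0.994). Of 7 plasma cell markers 3 were higher and 2 lower (3 and 3 adjusted over the list alone), with XBP1 at 1.40 and JCHAIN at -3.27 (adjusted p = 0.804). The alternative list test fry called the T and NK cell, plasma cell and fibroblast lists (adjusted p = 1.3e-07, 0.0452 and 1.6e-05). The medians of these 4 lists and of the LPS recognition list changed sign under at least 1 other scaling or summary.

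By limma, 8948 of the 27309 bovine sequences (32.8%) differed between the lines without LPS, 5129 higher and 3819 lower in TBL20, and 1994 differed by at least 2-fold, 923 higher and 1071 lower. With both species normalised together 14000 sequences passed and 17.8% of them were higher, and with the authors' values 14026 passed and 17.4% were higher, against 57.3% here. Those settings moved the median of all bovine sequences to -0.25 and -0.43 from 0.01, and median scaling moved it to 0.16 with 74.6% higher, so differences between the lines are relative to the bovine sequences as a whole.

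**Figure D1:**
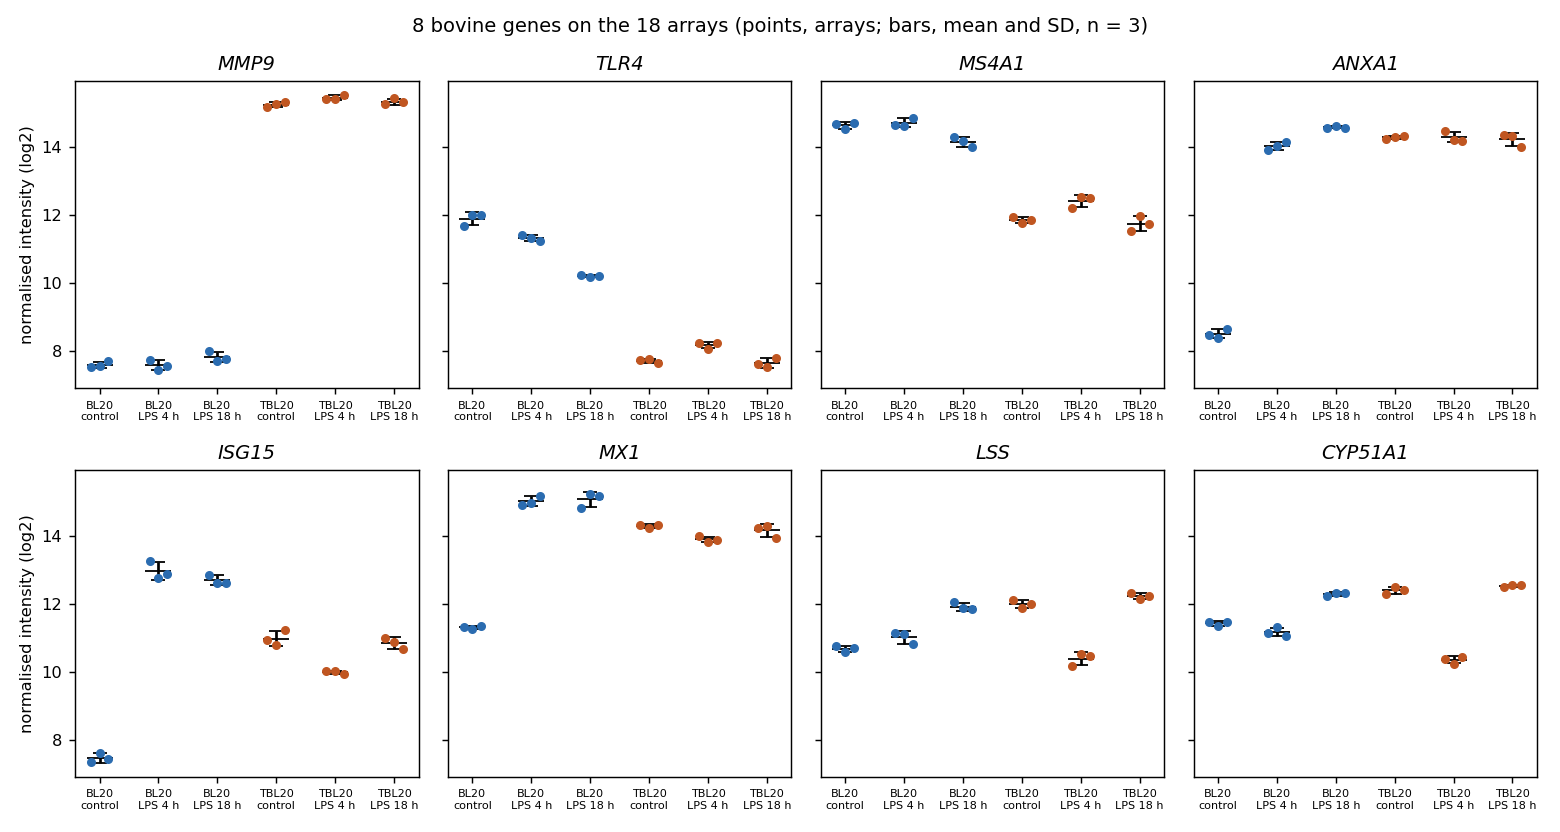
Normalised intensity (log2, vertical axis) of 8 bovine genes on each of the 18 arrays, by group, where points are arrays and bars the mean and SD of 3 arrays. MMP9 averaged 7.60 in BL20 control and 15.3 in TBL20 control, and ISG15 averaged 7.47 in BL20 control and 12.7 at 18 h after LPS, against 11.0 and 10.8 in TBL20.

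The response of uninfected cells to LPS was measured first at 4 h. CXCL10, a chemokine induced by interferon, rose 76.0-fold in BL20 (log2 change 6.25 ± 0.09, SE, n = 3 arrays per group), from a control near background. ISG15, a ubiquitin-like protein induced by interferon, rose 45.4-fold (5.50 ± 0.14), and ANXA1 45.9-fold (5.52 ± 0.11). MPEG1, which encodes a pore-forming macrophage protein, rose by 5.42 ± 0.11, and CD83, an activation marker of B cells and dendritic cells, by 4.92 ± 0.16. VCAM1, an adhesion molecule, was above background on no BL20 control array and rose at least 29.8-fold (adjusted p = 5.3e-16). The water channel gene AQP3 fell 18.3-fold (-4.20 ± 0.13), SPARC 11.9-fold (-3.57 ± 0.12) and RAG2, part of the recombinase of antigen receptor genes, 9.10-fold (-3.19 ± 0.11). GALNT4 (-3.15 ± 0.09), the scavenger receptor gene CD36 (-3.13 ± 0.10) and S1PR1, a receptor in lymphocyte egress (-3.11 ± 0.12), also fell. The adjusted p of the 12 genes lay between 4.3e-19 and 3.6e-13.

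Interferon-stimulated genes rose together at 4 h in BL20. Of 29 measured, 25 rose and 0 fell (25 and 0 adjusted over the list alone), with OAS2 at 4.85, MX2 at 4.74 and MX1 at 3.70, and the list median was 1.88 (camera adjusted p = 1.4e-36). The NF-kB list had 17 of 24 genes that rose and 0 that fell (17 and 0 adjusted over the list alone), with NFKB2 at 4.65, NFKBIZ at 3.67 and the inhibitor NFKBIA at 2.83 (camera adjusted p = 4.5e-21). AP-1 and immediate early genes had 10 of 15 that rose and 2 that fell (10 and 2 adjusted over the list alone), with JUND at 2.73 and JUN at 2.61 (camera adjusted p = 1.6e-07), while FOS gave 0.16 and passed with copy 2 of the probes alone (adjusted p = 0.0334). Of 36 cytokine and chemokine genes 11 rose and 4 fell (11 and 4 adjusted over the list alone), with CSF1 at 2.27, CCL4 at 1.96 and IL15 at 1.86. By camera the adjusted p of the list was 0.0034, the adjusted p = 0.106 with an estimated correlation, and 0.292 among genes above background on every array. TNF (0.03) and IL6 (-0.06) did not pass. IL10 (-0.35, adjusted p = 0.0325) passed, but not with BL20 control 1, 2 or 3 or BL20 LPS 4 h 2 or 3 left out (adjusted p = 0.0588 to 0.161). Apoptosis inhibitors had 5 of 12 that rose and 2 that fell (5 and 2 adjusted over the list alone), with BIRC3 at 2.61, CFLAR at 2.41 and BCL2A1 at least 7.56-fold higher (camera adjusted p = 0.0031). That call was lost among genes above background on every array (adjusted p = 0.103). Of 23 genes of the G1/S transition and DNA replication, 0 rose and 13 fell (0 and 14 adjusted over the list alone), with CCND3 at -1.28, UHRF1 at -1.21 and the inhibitors of the cell cycle CDKN2C at -1.38 and CDKN1B at -0.82 (camera adjusted p = 1.4e-05). IRF7 rose by 2.06.

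TLR4 fell by 0.56 on the log2 scale in BL20 at 4 h (adjusted p = 0.0003), a call that the second on-chip copy of the probes alone did not give (adjusted p = 0.103). LY96, the TLR4 partner MD-2, gave -0.52 (adjusted p = 0.0388), a call lost when BL20 control 1, 2 or 3 or BL20 LPS 4 h 1 or 2 was left out (adjusted p = 0.0593 to 0.203). MYC (-0.25), MS4A1 (0.08), CD79A (-0.39), MMP9 (-0.02) and MMP13 (0.10) did not pass, though CD79A passed under 2 alternatives (adjusted p = 0.0185 to 0.0308). By limma 5736 sequences (21.0%) changed, 2734 up and 3002 down, and 1145 changed at least 2-fold, 575 up and 570 down. Median scaling gave 3220.

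At 18 h after LPS the interferon-stimulated genes of BL20 were still raised, and cholesterol synthesis genes rose as well. ANXA1 was 67.7-fold higher than in the control (log2 change 6.08 ± 0.11, SE, n = 3 per group), ITGA6, an integrin subunit, 38.5-fold (5.27 ± 0.11) and ISG15 37.7-fold (5.23 ± 0.14). OAS1Y rose 31.9-fold (4.99 ± 0.11), MX2 29.5-fold from a control near background (4.88 ± 0.11) and MPEG1 21.5-fold (4.43 ± 0.11). AQP3 fell 22.9-fold (-4.52 ± 0.13), the protease gene CTSW 9.57-fold (-3.26 ± 0.12) and CD36 9.51-fold (-3.25 ± 0.10). STXBP6 fell 9.48-fold (-3.25 ± 0.18), CAMKV 9.23-fold (-3.21 ± 0.15) and LOC534967, a gene without a given name, 9.14-fold (-3.19 ± 0.12). Their adjusted p lay between 7.8e-18 and 6.8e-11.

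Of 29 interferon-stimulated genes 28 rose and 0 fell at 18 h in BL20 (28 and 0 adjusted over the list alone), with OAS2 at 4.10 and MX1 at 3.77 (camera adjusted p = 9.8e-38), and IRF7 (1.17) rose. The NF-kB list had 14 of 24 genes that rose and 1 that fell (15 and 1 adjusted over the list alone), with NFKB2 at 3.28, NFKBIZ at 2.87 and NFKBIA at 1.33 (camera adjusted p = 2.8e-11). TNF, a cytokine gene outside that list, had a change of -1.71. AP-1 and immediate early genes had 9 of 15 that rose and 2 that fell (9 and 3 adjusted over the list alone), with JUND at 2.14 and JUN at 1.31 (camera adjusted p = 0.00077). Apoptosis inhibitors had 5 of 12 that rose and 2 that fell (5 and 3 adjusted over the list alone), with BIRC3 at 1.65 and BCL2A1 at least 3.47-fold higher (camera adjusted p = 0.0107). Of 21 cholesterol biosynthesis genes 19 rose and 0 fell (19 and 0 adjusted over the list alone), with LSS at 1.23, INSIG1 at 1.14 and SC5D at 1.04, and the list median was 0.74 (camera adjusted p = 5.9e-12). MHC class II genes had 4 of 10 that rose and 0 that fell (4 and 0 adjusted over the list alone), led by BOLA-DYA at 3.83 and BOLA-DYB at 1.47 (camera adjusted p = 0.002). The calls of the apoptosis inhibitor and MHC class II lists were lost among genes above background on every array (adjusted p = 0.115 and 0.214).

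In BL20 at 18 h more genes fell than rose in the lists of G1/S and DNA replication and of MYC and ribosome biogenesis. Of 23 G1/S and DNA replication genes 1 rose and 13 fell (1 and 15 adjusted over the list alone), with UHRF1 at -1.42, MCM5 at -0.84 and PCNA at -0.75 (camera adjusted p = 0.00031). MYC fell by 1.05 on the log2 scale. Of 23 MYC and ribosome biogenesis genes 1 rose, the MYC antagonist MXI1 (0.90), and 13 fell (1 and 14 adjusted over the list alone), with ODC1 at -0.85 and RRP9 at -0.71. Their camera adjusted p was 0.003, and the adjusted p = 0.104 with an estimated correlation. Hypoxia-inducible genes had 9 of 19 that rose, among them EPAS1 (2.82) and SLC2A3 (1.59), and 3 that fell, among them NDRG1 (-1.32), and 9 and 3 adjusted over the list alone. Their camera adjusted p was 0.00077, and the adjusted p = 0.0534 with an estimated correlation. TLR4 fell by 1.68 and LY96 by 0.82, the latter with an adjusted p of 0.0014 that became 0.051 under median scaling. IL10 (-0.42) and MS4A1 (-0.48) fell and lost their calls under median scaling and with copy 2 of the probes alone (adjusted p = 0.0713 to 0.209). MMP13 rose by 0.58, and MMP9 (0.23), FOS (0.23), IL6 (0.06) and CD79A (-0.28) did not pass, though MMP9 passed under 4 alternatives (adjusted p = 0.0062 to 0.0497). By limma 7990 sequences (29.3%) changed, 4041 up and 3949 down, and 1026 changed at least 2-fold, 639 up and 387 down. Median scaling gave 3924 with 62.7% up against 50.6% here, and copy 2 of the probes gave 5237.

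The change from 4 h to 18 h in BL20 shows which parts of the response faded. Of 24 NF-kB pathway and target genes 1 rose and 16 fell (1 and 18 adjusted over the list alone), with VCAM1 at -3.62, CD83 at -3.07 and NFKBIA at -1.50 (camera adjusted p = 1.5e-11). MYC and ribosome biogenesis genes had 14 of 23 that fell and 0 that rose (15 and 1 adjusted over the list alone), with PPAN at -1.06 and RRP9 at -0.95 (camera adjusted p = 1.2e-06). Cholesterol biosynthesis genes had 19 of 21 that rose and 0 that fell (19 and 0 adjusted over the list alone), with INSIG1 at 1.51 and CYP51A1 at 1.11 (camera adjusted p = 2.1e-15). MHC class II genes had 6 of 10 that rose and 0 that fell (6 and 0 adjusted over the list alone), with BOLA-DYA at 2.93 and BOLA-DOB at 2.50 (camera adjusted p = 2.0e-06). Hypoxia-inducible genes had 10 of 19 that rose and 3 that fell (11 and 3 adjusted over the list alone), with SLC2A3 at 2.86 and BNIP3 at 1.70 (camera adjusted p = 5.9e-05). Mitotic genes of the G2/M list had 10 of 22 that rose and 0 that fell (12 and 1 adjusted over the list alone), with PLK1 at 0.57 and AURKA at 0.53 (camera adjusted p = 0.00065). By limma 6787 sequences changed between the times, 3690 up and 3097 down, and 710 at least 2-fold. Median scaling gave 3395 with 71.5% up against 54.4% here.

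In infected cells the response to LPS at 4 h was small, and its clearest part was a fall of cholesterol synthesis genes. CYP51A1, the sterol demethylase, fell 4.14-fold in TBL20 (log2 change -2.05 ± 0.09, SE, n = 3 per group). FDFT1, squalene synthase, fell 3.09-fold (-1.63 ± 0.10) and LSS 3.06-fold (-1.61 ± 0.11). The acetyl-CoA synthetase gene ACSS2 fell 3.44-fold (-1.78 ± 0.11) and INSIG1, a regulator of sterol synthesis, 2.95-fold (-1.56 ± 0.11). Of 21 cholesterol biosynthesis genes 20 fell and 0 rose (20 and 0 adjusted over the list alone), with a list median of -1.10 (camera adjusted p = 1.2e-47). PRSS54, a protease gene, rose 3.16-fold (1.66 ± 0.14), IL1R2, the decoy receptor of interleukin 1, 2.94-fold (1.55 ± 0.12) and the chemokine receptor gene CCR1 2.75-fold (1.46 ± 0.15). CRTAM rose 2.69-fold (1.43 ± 0.12), the interleukin 1 receptor antagonist gene IL1RN 2.67-fold (1.42 ± 0.12) and the potassium channel gene KCNE4 2.43-fold (1.28 ± 0.11). The adjusted p of the 11 genes lay between 1.1e-10 and 8.5e-06.

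At 4 h in TBL20, 5 of 24 NF-kB pathway and target genes rose and 0 fell (8 and 0 adjusted over the list alone), with GADD45B at 0.81, BCL2A1 at 0.62 and NFKBIZ at 0.56. Their camera adjusted p was 0.0014, and the adjusted p = 0.398 with an estimated correlation. BCL2A1 and NFKBIZ did not pass under median scaling (adjusted p = 0.0556 and 0.386). Of 29 interferon-stimulated genes 1 rose, MX2 (0.49), and 4 fell, among them ISG15 (-0.99), IFI6 (-0.69) and IFITM1 (-0.58), and 1 and 6 adjusted over the list alone (camera adjusted p = 0.324). MX2 lost its call under 7 other settings (adjusted p = 0.051 to 0.538), and without TBL20 control 2 or 3 or TBL20 LPS 4 h 2 or 3 (0.0566 to 0.072). IFI6 lost it under median scaling (adjusted p = 0.077) and without TBL20 control 3 (0.0589). MYC (0.80), MS4A1 (0.57), MMP13 (0.56) and TLR4 (0.46) rose, but none of the 4 passed under median scaling. TLR4 also did not pass without TBL20 control 3 (adjusted p = 0.0561) or TBL20 LPS 4 h 3 (0.0548), nor MMP13 without TBL20 control 2 or TBL20 LPS 4 h 2 (0.0544 to 0.0631). JUN (0.59), FOS (0.34), NFKBIA (0.35), MX1 (-0.39), IRF7 (-0.24), TNF (-0.03), IL6 (0.16), IL10 (0.09), LY96 (-0.10), MMP9 (0.21) and CD79A (0.01) did not pass. Under other settings JUN and MX1 passed in 7 each (adjusted p = 0.0023 to 0.043 and 0.0071 to 0.0485), FOS in 6 (0.002 to 0.0428) and NFKBIA in 4 (0.0235 to 0.0446).

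By limma 1383 sequences (5.06%) changed at 4 h in TBL20, 820 up and 563 down, and 72 changed at least 2-fold, 41 up and 31 down. Within the first scan batch 926 passed and with scan batch as a block 1076. Median scaling gave 276, a fit of these groups alone 2157, array weights 3054, and copies 1 and 2 of the probes 725 and 566. Leaving out an array gave 905, 716 or 666 without TBL20 control 1, 2 or 3 and 759, 803 or 678 without TBL20 LPS 4 h 1, 2 or 3.

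The late response of infected cells was measured at 18 h. MGC148328, a gene without a given name, rose 4.25-fold (log2 change 2.09 ± 0.30, SE, n = 3 per group), ALDH1A1, a retinaldehyde dehydrogenase, 3.26-fold (1.70 ± 0.13), and CCL22, a chemokine that attracts T cells, 2.93-fold (1.55 ± 0.13). PLAU, the urokinase plasminogen activator, rose 2.84-fold (1.51 ± 0.12), IL1RN 2.83-fold (SE 0.12) and CRTAM 2.71-fold (1.44 ± 0.12). The falls were smaller. ZNF12 fell 2.01-fold (-1.01 ± 0.12), gzmA, a granzyme gene of a multigene family whose identity is uncertain, 1.91-fold (-0.93 ± 0.11) and ALOX5AP, the 5-lipoxygenase activating protein, 1.90-fold (-0.93 ± 0.10). LOC509810 fell 1.88-fold (-0.91 ± 0.13), DMP1 1.77-fold (-0.83 ± 0.10) and CD34 1.74-fold (-0.80 ± 0.13). Adjusted p lay between 3.4e-07 and 0.0012. The call of gzmA was lost with the authors' values (adjusted p = 0.0566), that of LOC509810 within the first scan batch, where 18 h after LPS is 1 array (0.0806), and that of CD34 with the mean of probes or copy 1 (0.0558 to 0.0958).

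At 18 h in TBL20, 5 of 24 NF-kB pathway and target genes rose and 0 fell (12 and 0 adjusted over the list alone), with BCL2A1 at 1.12, ICAM1 at 0.61, NFKB2 at 0.57 and NFKBIZ at 0.51 (camera adjusted p = 5.0e-09). Apoptosis inhibitors had 2 of 12 that rose, BCL2A1 and PIM1 (0.54), and 0 that fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.0019). Under median scaling that list's median was -0.28 against 0.04 here, and it did not pass (adjusted p = 0.395). Cell adhesion genes had 4 of 32 that rose, among them SELP (1.15), ITGAL (0.66) and ICAM1, and 0 that fell (4 and 0 adjusted over the list alone; camera adjusted p = 0.00028). That call was lost under median scaling, with a median of -0.20 against 0.09 (adjusted p = 0.22), and within the first scan batch, where the 18 h group is 1 array (adjusted p = 0.185). ICAM1, NFKB2, NFKBIZ, PIM1, ITGAL, NFKBIA (0.51, adjusted p = 0.0402) and MMP13 (0.76, adjusted p = 0.0017) did not pass under median scaling, nor, except ITGAL, within the first scan batch. There the changes of ICAM1 (0.66), NFKB2 (0.61) and NFKBIA (0.72) were as large, and those of NFKBIZ (0.32), PIM1 (0.41) and MMP13 (0.53) were smaller in the same direction. With scan batch as a block, which keeps all arrays, the calls of ICAM1 (adjusted p = 0.061), NFKB2 (0.15), NFKBIZ (0.21), PIM1 (0.11), MMP13 (0.0584), NFKBIA (0.0836) and IFI6 (0.325) were lost as well, with changes that stayed similar for ICAM1 (0.59), NFKB2 (0.56), PIM1 (0.56) and NFKBIA (0.62) and were smaller for NFKBIZ (0.41), MMP13 (0.60) and IFI6 (-0.45). Interferon-stimulated genes had 1 of 29 that rose, GBP5 (0.65), and 1 that fell, IFI6 (-0.54, adjusted p = 0.0481), and 1 and 3 adjusted over the list alone. Their median was -0.07, their mean -0.02 and the test pointed upward (camera adjusted p = 0.874). GBP5 did not pass under median scaling or with copy 2 of the probes (adjusted p = 0.0794 to 0.12).

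Single arrays decided some of these calls at 18 h. NFKB2 did not pass without TBL20 control 1 or 2 or TBL20 LPS 18 h 1 or 2 (adjusted p = 0.0553 to 0.0967). NFKBIZ did not pass without TBL20 control 2 or 3 or TBL20 LPS 18 h 1 or 3 (adjusted p = 0.0602 to 0.0815), nor PIM1 without TBL20 control 1 or 3 or TBL20 LPS 18 h 1 or 3 (0.0502 to 0.0871). NFKBIA did not pass without TBL20 control 1, 2 or 3 or TBL20 LPS 18 h 1 or 2 (adjusted p = 0.0728 to 0.147), nor IFI6 without TBL20 control 1, 2 or 3 or TBL20 LPS 18 h 1 or 3 (0.0609 to 0.214). MX1 (-0.13), ISG15 (-0.13), IRF7 (-0.12), JUN (0.43), FOS (0.19), MYC (0.23), TNF (0.08), IL6 (0.01), IL10 (-0.03), TLR4 (-0.07), LY96 (-0.54), MMP9 (0.09), MS4A1 (-0.11) and CD79A (-0.27) did not pass. LY96 passed under 3 alternatives (adjusted p = 0.0423 to 0.0434), and MX1 and CD79A passed under median scaling (0.0462 and 0.0261). By limma 872 sequences (3.19%) changed, 577 up and 295 down, and 123 changed at least 2-fold, 122 up and 1 down, which was ZNF12. Within the first scan batch, with 1 array at 18 h, 407 passed, with scan batch as a block 284, in a fit of these groups alone 472, with the mean of probes 1317, with copies 1 and 2 of the probes 549 and 383, and without the 4 arrays of high background 463. Median scaling gave 2619 with 9.58% up against 66.2% here and moved the median of all sequences to -0.13 from -0.01. Leaving out TBL20 control 1, 2 or 3 or TBL20 LPS 18 h 1 gave 560, 437, 415 or 438.

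Between 4 h and 18 h in TBL20 the cholesterol genes rose. Of 21 measured, 20 rose and 0 fell (20 and 0 adjusted over the list alone), with CYP51A1 at 2.18, PMVK at 1.84 and LSS at 1.84 (camera adjusted p = 1.4e-54). Hypoxia-inducible genes had 7 of 19 that rose and 1 that fell, JMJD6 (-0.52), and 9 and 1 adjusted over the list alone (camera adjusted p = 8.1e-06). SLC2A3 (0.96) and VEGFA (0.86) did not pass under median scaling (adjusted p = 0.0721 and 0.101), and BNIP3 (1.11) did not pass within the second scan batch, where 4 h is 1 array (change 0.82, adjusted p = 0.122). JMJD6 did not pass without TBL20 LPS 4 h 1 or 2 or TBL20 LPS 18 h 1 or 3 (adjusted p = 0.0506 to 0.0928), and it lost its call under 6 other settings. Of 22 G2/M genes 4 fell and 0 rose (11 and 0 adjusted over the list alone), among them CCNB1 (-0.45), and the camera adjusted p was 6.9e-06. Within each scan batch, where 1 of the times is a single array, the change of CCNB1 was -0.48 and -0.40 and did not pass (adjusted p = 0.0543 and 0.227). The other 3 were less stable. CDK1 (-0.55) did not pass without TBL20 LPS 4 h 1 or 3 or TBL20 LPS 18 h 2 (adjusted p = 0.0672 to 0.0819), nor NUSAP1 (-0.43) without TBL20 LPS 4 h 1 or TBL20 LPS 18 h 2 (0.0528 to 0.072), nor KIF23 (-0.37) without any 1 of the 6 arrays (0.0524 to 0.148). Other settings ended their calls in 4, 4 and 11 cases. By limma 1547 sequences changed, 738 up and 809 down, and 118 at least 2-fold. Within the first scan batch, with 1 array at 18 h, 748 passed, within the second, with 1 array at 4 h, 163, and with scan batch as a block 1105. Median scaling gave 997 with 21.8% up against 47.7% here, a fit of these groups alone 804, and copies 1 and 2 of the probes 991 and 669. Leaving out TBL20 LPS 4 h 1, TBL20 LPS 4 h 3 or TBL20 LPS 18 h 1 gave 701, 835 or 845.

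The interaction asks directly whether the response to LPS differed between the lines. At 18 h, genes with a large rise in BL20 had the lowest values. The response of ANXA1 in TBL20 minus that in BL20 was -6.14 ± 0.15 (log2, SE, n = 3 per group), that of ISG15 -5.37 ± 0.19, OAS1Y -5.17 ± 0.15, ITGA6 -4.97 ± 0.15, MX2 -4.85 ± 0.16 and CXCL10 -4.63 ± 0.13. In that order, their levels in TBL20 control were 14.3, 11.0, 11.4, 12.9, 10.6 and 9.47. BL20 control had 8.51, 7.47, 8.34, 9.35, 6.80 and 6.92, and BL20 at 18 h 14.6, 12.7, 13.3, 14.6, 11.7 and 11.4. Part of the BL20 rise of these genes was thus already present in TBL20 without LPS. Genes with a large fall in BL20 had positive values, with AQP3 at 4.30 ± 0.19, CTSW at 3.50 ± 0.17, STXBP6 at 3.48 ± 0.26, CD36 at 3.26 ± 0.14, SPARC at 3.11 ± 0.17 and GALNT4 at 3.09 ± 0.13. In the TBL20 control CD36 (7.17), CTSW (8.06), AQP3 (8.72) and TLR4 (7.72) lay too close to the background threshold of 6.94 to fall as far as in BL20, so their positive values are partly set by that floor. Adjusted p lay between 3.7e-15 and 9.5e-09. MX1 (-3.90), IRF7 (-1.29), TLR4 (1.61) and TNF (1.78) also passed. MYC (1.27) passed but not under median scaling (adjusted p = 0.0961), and BCL2A1 (-0.95, a fitted value with BL20 controls at background) not without background correction (0.101). NFKBIA (-0.82) passed but not with copy 1 of the probes or within the first scan batch, where TBL20 at 18 h is 1 array (adjusted p = 0.0799 and 0.0917). JUN (-0.88, adjusted p = 0.0245) did not pass within the first scan batch or with scan batch as a block (0.108), nor without BL20 control 2 or 3, TBL20 control 3, BL20 LPS 18 h 1 or TBL20 LPS 18 h 3 (0.0525 to 0.0737). FOS (-0.04), IL6 (-0.05), IL10 (0.39), LY96 (0.28), MMP9 (-0.14), MMP13 (0.17), CD79A (0.02) and MS4A1 (0.37) did not pass, though IL10 and MMP13 passed under 2 alternatives each (adjusted p = 0.0322 to 0.0476 and 0.0061 to 0.0472) and MMP9 under median scaling (0.0486).

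Of 29 interferon-stimulated genes, 27 had a lower response in TBL20 than in BL20 and 0 a higher response at 4 h (27 and 0 adjusted over the list alone), with a list median of -1.62 (camera adjusted p = 1.3e-40). At 18 h the numbers were 27 and 0 (28 and 0 adjusted over the list alone), with a median of -1.44 (camera adjusted p = 7.2e-40). NF-kB pathway and target genes had 16 of 24 with a lower response in TBL20 and 0 with a higher response at 4 h (16 and 1 adjusted over the list alone; camera adjusted p = 1.9e-17). At 18 h 11 were lower and 0 higher (13 and 3 adjusted over the list alone; camera adjusted p = 1.5e-06), and the adjusted p = 0.0588 with an estimated correlation. NFKB2 was at -4.61 and -2.70. AP-1 and immediate early genes had 10 of 15 lower and 1 higher at 4 h (10 and 1 adjusted over the list alone; camera adjusted p = 8.3e-08), with JUND at -3.17 and JUNB at -2.61. Cholesterol genes had 17 of 21 lower and 0 higher at 4 h (18 and 0 adjusted over the list alone; median -1.10, camera adjusted p = 3.5e-15). At 18 h 15 were lower and 0 higher (17 and 0 adjusted over the list alone; median -0.65, camera adjusted p = 2.1e-08). G1/S genes had 8 of 23 higher and 0 lower at 4 h (11 and 0 adjusted over the list alone; camera adjusted p = 0.00017), with CCND3 at 1.33. MHC class II genes had 4 of 10 lower and 0 higher at 18 h (4 and 0 adjusted over the list alone), with BOLA-DYA at -3.75. Their camera adjusted p was 0.0024, the adjusted p = 0.0588 with an estimated correlation, and 0.273 among genes above background on every array.

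By limma 3705 sequences differed in their response at 4 h, 2018 higher in TBL20 and 1687 lower, and 3451 at 18 h, 1643 higher and 1808 lower. By at least 2-fold, 1198 differed at 4 h and 943 at 18 h. Of the 639 sequences that rose at least 2-fold in BL20 at 18 h, with a median of 1.47, the median in TBL20 was 0.12 and 77.6% passed the interaction test. Of the 387 that fell at least 2-fold, with a median of -1.37, the median in TBL20 was -0.05 and 96.6% passed, but 35.1% of them lay within 1 log2 unit of the background threshold in TBL20, where a 2-fold fall could not be seen. Within the first scan batch 3436 sequences passed at 4 h and 2548 at 18 h, where TBL20 at 18 h is 1 array. Median scaling gave 1711 at 4 h and copy 2 of the probes 2140 at 18 h. Under median scaling 15.9% of those called at 18 h were higher against 47.6% here, and the median of all sequences was -0.17.

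**Figure D2:**
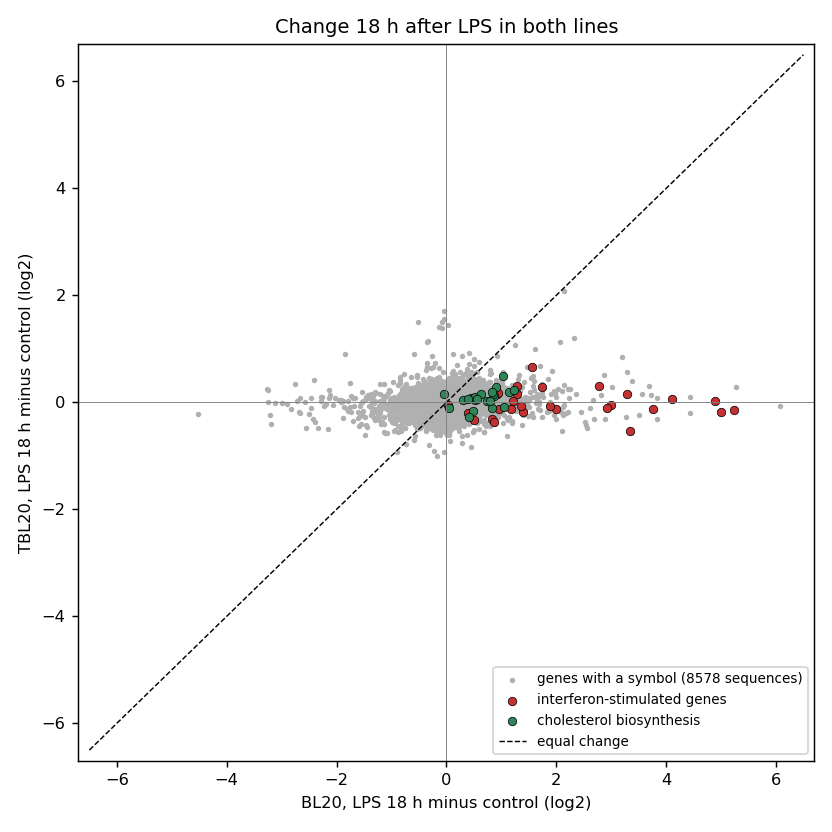
Change 18 h after LPS against control (log2) in BL20 (horizontal axis) and in TBL20 (vertical axis), n = 3 arrays per group. Points are the 8578 sequences with a gene symbol (red, interferon-stimulated genes, and green, cholesterol biosynthesis genes), the dashed line marks equal change, and ISG15 sits at 5.23 in BL20 and -0.13 in TBL20.

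After LPS the lines were also compared at each time. Interferon-stimulated genes were lower in TBL20 than in BL20 under LPS. At 4 h 22 of 29 were lower and 2 higher (22 and 2 adjusted over the list alone; median -1.17, camera adjusted p = 3.5e-12), with OAS2 at -3.90 and ISG15 at -2.98. At 18 h 21 were lower and 3 higher (21 and 3 adjusted over the list alone; median -0.81, camera adjusted p = 1.1e-08), with IFI6 at -3.29 and RTP4 at 2.41. At 18 h MHC class II genes had 7 of 10 lower and 0 higher (8 and 0 adjusted over the list alone), with BOLA-DYA at -4.39 (camera adjusted p = 1.0e-06). B cell markers had 12 of 16 lower and 1 higher (13 and 1 adjusted over the list alone), with BLK at -5.18, JCHAIN at -5.10 and CD79A at -2.46 (camera adjusted p = 2.3e-09). By limma 8962 sequences differed at 4 h, 5135 higher and 3827 lower in TBL20, and 10203 at 18 h, 5329 higher and 4874 lower. Within the first scan batch 8510 and 8557 passed, the latter with 1 TBL20 array. With both species normalised together 13748 passed at 4 h and 13832 at 18 h (18.2% and 18.3% higher, against 57.3% and 52.2% here). With the authors' values 13752 and 13803 passed (18.0% higher in each, medians of all sequences -0.42 and -0.41), and median scaling gave 71.4% and 39.9% higher.

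**Figure D3:**
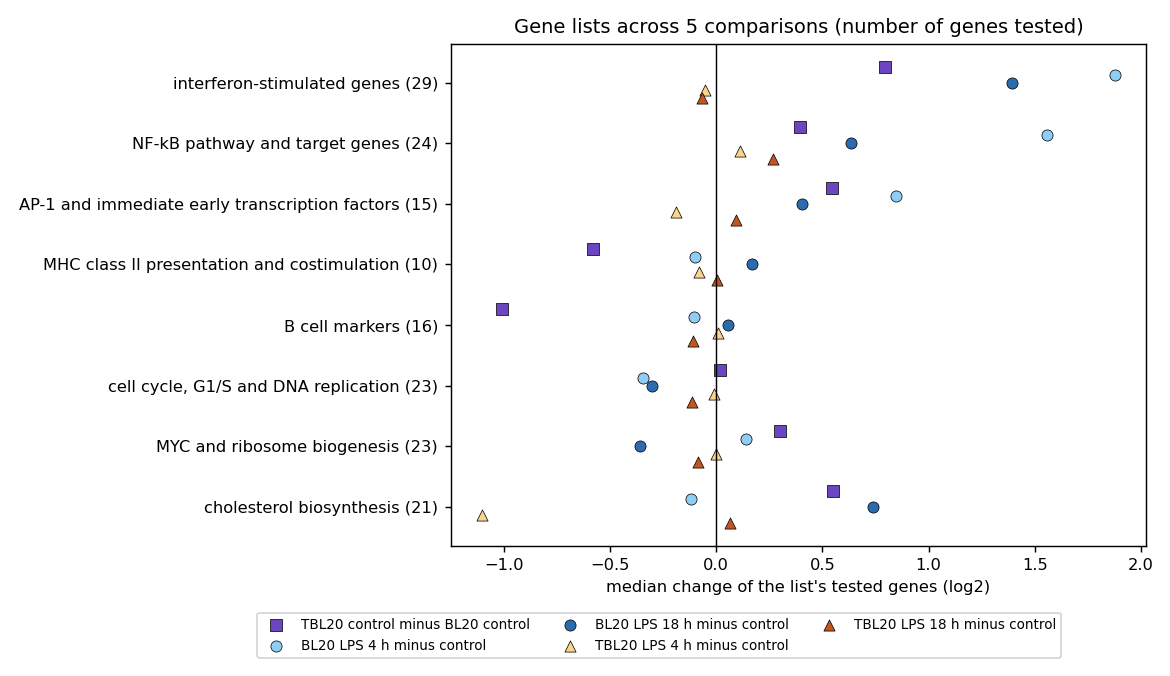
Median change (log2, horizontal axis) of the tested genes of 8 fixed lists in 5 comparisons, with the number of genes tested beside each list name, where each symbol is 1 comparison of groups of 3 arrays. Interferon-stimulated genes had medians of 1.88 and 1.39 in BL20 after LPS and -0.05 and -0.07 in TBL20, and cholesterol genes had a median of -1.10 at 4 h in TBL20.

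Over all 11 comparisons and 30 lists, camera made 97 list calls with its preset correlation, and 39 of these 97 held with an estimated correlation. Those described here held with it wherever no such p is given beside the call.

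Across genes, which are not independent replicates, the responses of the lines at 18 h correlated with Pearson r = 0.251 and Spearman rho = 0.184 over 27309 sequences, with a slope of 0.123 for TBL20 on BL20. The value within the first scan batch, with 1 TBL20 array at 18 h, was 0.203, and under median scaling it was 0.12. Both lines had 367 sequences up and 100 down at 18 h, against 85.4 and 42.7 for independent calls. At 4 h the correlation was 0.131 (rho 0.174), with 265 up and 190 down in both and 190 in opposite directions, against 82.1, 61.9 and 146.5 for independent calls. The infection difference and the 18 h response of BL20 correlated with r = 0.285 (rho 0.236) and share the BL20 control arrays. Simulated groups with no difference and the same sharing gave r = 0.501 and rho = 0.476 from noise alone, and a covariance of 0.009 against 0.0897 here. Of the sequences called in both comparisons with shared controls, 1167 were higher and 1355 lower in both and 1255 went opposite ways, against 759, 552 and 1307 for independent calls. Shared controls by themselves favour the same direction (66.6% same sign in the simulated groups). The figures for independent calls do not allow for this and are no chance level here.

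Parasite sequences were tested among themselves on the 9 TBL20 arrays. At 18 h after LPS 340 of 3489 changed, 253 up and 87 down, 41 of them up at least 2-fold and 0 down as much. TA14210 rose from a low control level (6.90) by about 2.98 ± 0.24 (log2, SE, n = 3 per group, adjusted p = 1.5e-05) and TA16580 by 2.19 ± 0.17 (adjusted p = 1.4e-05). TA04840 fell by 0.74 (adjusted p = 0.00042), a call lost with both species normalised together (adjusted p = 0.0595). TA04415 fell by 0.61 (adjusted p = 0.0055), a call lost in that setting and with the authors' values (adjusted p = 0.139 to 0.175). The files pair these identifiers with no gene names. At 4 h 15 changed, 13 up and 2 down, against 347 at an unadjusted p under 0.05. TA17550 and TA09840 rose by 0.81 each, and TA04960 and TA10990 had changes of -0.56 each. All 4 calls were lost under median scaling, with both species normalised together and with the authors' values. In the latter 2 settings the changes of TA17550 (0.82 and 0.97), TA09840 (1.21 and 1.45) and TA04960 (-0.69 and -1.005) were no smaller.

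At 18 h the parasite count was 781 within the first scan batch, where that group is 1 array of high background, of which 52.0% were up against 74.4% here, and 135 with scan batch as a block. With median scaling 45.3% were up. The count was 180, 151, 212 or 608 without TBL20 control 1, TBL20 control 2, TBL20 LPS 18 h 1 or TBL20 LPS 18 h 3. At 4 h it was 11 within the first scan batch, 5 with scan batch as a block, 6 with the replicate number as a block, 2 under median scaling and 9 without the 2 TBL20 arrays of high background. It was 5, 2 or 2 without TBL20 control 1, 2 or 3 and 7, 3 or 4 without TBL20 LPS 4 h 1, 2 or 3. TA04960 and TA10990 did not pass without any 1 of these 6 arrays (adjusted p = 0.0847 to 0.23), nor TA09840 without TBL20 control 2 or 3 or TBL20 LPS 4 h 2 (0.0642 to 0.0697).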

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

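The splits of the samples, the scan batch test of the cholesterol genes and the probe test of parasite RNA were planned, and the other tests of explanations below were chosen only after the result was seen.

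The following results differed between the lines in a direct test of the LPS response of TBL20 minus that of BL20. At 4 h 3705 sequences differed and at 18 h 3451. Genes at 18 h with a positive value (log2) were AQP3 (4.30), CTSW (3.50), STXBP6 (3.48), CD36 (3.26), SPARC (3.11), GALNT4 (3.09), TNF (1.78), TLR4 (1.61) and MYC (1.27). Those with a negative value were ANXA1 (-6.14), ISG15 (-5.37), OAS1Y (-5.17), ITGA6 (-4.97), MX2 (-4.85), CXCL10 (-4.63), MX1 (-3.90), IRF7 (-1.29), BCL2A1 (-0.95, with BL20 controls at background), JUN (-0.88) and NFKBIA (-0.82). List medians at 4 h were -1.62 for interferon-stimulated genes, -1.42 for NF-kB genes, -1.16 for AP-1 genes, 0.34 for G1/S genes and -1.10 for cholesterol genes. At 18 h they were -1.44 for interferon-stimulated, -0.41 for NF-kB, -0.65 for cholesterol and -0.35 for MHC class II genes. Under median scaling these 18 h medians were -1.63, -0.79, -1.09 and -0.77, and the median of all sequences was -0.17. With an estimated correlation the NF-kB and MHC class II lists did not pass at 18 h (adjusted p = 0.0588 each), nor did MHC class II among genes above background on every array (0.273). Outside the comparisons, 7 of 3770 parasite sequences exceeded the background threshold on all 9 BL20 arrays, where no parasite is present. Their values were log2 6.95 to 9.08, the brightest being TA21060. The threshold was set at the 95th percentile of these same sequences on these arrays, so some exceed it by construction.

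Other splits of the samples were counted for each comparison. For 3 arrays against 3, the 10 splits are too few for a share under 0.05. The real count and the highest of the other splits were 8948 and 0 for TBL20 against BL20 without LPS, 8962 and 0 at 4 h and 10203 and 1 at 18 h. They were 5736 and 0 for BL20 at 4 h, 7990 and 0 for BL20 at 18 h, 1383 and 0 for TBL20 at 4 h and 872 and 2 for TBL20 at 18 h. For 18 h against 4 h they were 6787 and 0 in BL20 and 1547 and 2 in TBL20, and for the parasite 15 and 0 at 4 h and 340 and 12 at 18 h. In each of these 1 split, the real one, gave as many. For the interaction at 4 h, 1 of 100 drawn splits, the real one, gave as many as 3705 (highest other 3275), but 93 draws mixed the BL20 arrays and so removed the BL20 response (at most 153). The 6 other draws that kept the BL20 groups gave 2775 to 3275 and are too few for a share under 0.05, so the draws test mainly the BL20 response and do not exclude chance for the grouping of the TBL20 arrays. At 18 h 8 of 100 gave as many as 3451 (highest other 6187), so the count does not exclude chance. In the 7 others the BL20 arrays kept their real groups or were exchanged whole, so the BL20 response stayed in the contrast, and in 90 draws that mixed the BL20 arrays the highest was 28. The draw of 6187 kept the real groups of both lines, with those of 1 line exchanged, so its contrast summed the responses of the lines. The draws at 18 h thus cannot decide on chance.

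The LPS response was smaller in TBL20 than in BL20, and noise in the TBL20 arrays that hides a response of the BL20 size is argued against by the slope across genes of the TBL20 on the BL20 change at 18 h, 0.133 after correction for noise (0.116 to 0.152 with an array left out), since noise in TBL20 leaves a slope at 1. Compression of bovine signals on TBL20 arrays is argued against by the ratio of their spread to that on BL20 arrays, 0.972 (0.805 for the lowest array, TBL20 LPS 18 h 2), far above the slope. For genes raised by LPS in BL20 the median infection difference was 0.0654 of the median LPS change, which argues against an already raised level for the set as a whole, though 15.96% of the 639 had at least 0.8 of it, among them ANXA1 (14.3 in TBL20 control, 14.6 in BL20 at 18 h) and IL2RA (10.5 in both), chosen after their values were seen. For genes lowered by LPS the ratio was 1.06, so an already low level may account for many of the missing falls and an already high level for a part of the missing rises. Interferon-stimulated genes had a list median of 0.80 in the infection difference, against 1.39 in the BL20 response at 18 h. A lower response to LPS in infected cells, for which the low TLR4 (-4.17) is a candidate explanation that was not tested, stays open as a hypothesis, along with any difference between the lines other than the infection.

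Cholesterol synthesis genes fell at 4 h in TBL20. For handling that acts alike on both lines, such as the fresh medium, the interaction had a median of -1.10 and 17 members past the test. List medians on the BL20 arrays at 4 h were -0.01, -0.13 and -0.10. These values argue against such handling as the only effect in both lines. A shared fall that LPS offset in BL20 would give the same values, so the interaction cannot exclude it and it stays open. A scan batch difference is argued against by a median of -1.08 within the first scan batch. An effect of the medium on infected cells alone also stays open, since no control was taken at the same time. So does an effect of LPS on sterol synthesis in infected cells, as a hypothesis.

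Many genes were higher in TBL20 than in BL20 without LPS. For parasite RNA bound by bovine probes, the probes of a sequence were counted. Of sequences at least 2-fold higher, 96.0% had 4 or 5 probes up, against 94.9% with 4 or 5 probes down among those lower. These sequences were chosen by a summary of the same probes, so most of their probes had to agree. Parasite RNA bound by most probes of a sequence would give a like share, so the test cannot decide and this stays open. The test for T or NK cells among the TBL20 cells asked every T and NK marker dim in BL20 to rise by at least 2-fold. Neither cell type need express all of them, so the test cannot decide and such cells stay open. Of the 18 markers, 12 lay below a 2-fold rise by over 2 standard errors, such as CD3E (-0.19) and CD8A (-0.12). IL2RA (3.16), NKG7 (3.23), CD28 (at least 10.9-fold), KLRK1 (2.49), GZMA (2.25) and CD2 (1.44) were higher. Expression of these genes by the infected cells themselves stays open as a hypothesis, as do other differences between the lines that arose in culture, which were not tested.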

How the results depend on the processing

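The settings within a scan batch, without arrays of high background and with scan batch as a block for the parasite were chosen only after the data were seen. For the genes covered by the naming rule, including list members not printed in the text, 5937 of 6150 values under an alternative kept their direction and side of the threshold, 170 lost their call, 43 gained one and 0 reversed, and of 2538 values with an array left out 2446 kept both and 92 lost their call. For lists 1071 of 1109 kept both, 32 lost and 5 gained a call and 1 reversed, and all 396 values with an array left out kept both. The 1 reversed was the fibroblast, endothelial and epithelial list, where fry pointed upward and camera downward with the same list median (-0.033). The causes of the changes below were not tested, except that a stricter threshold calls fewer sequences by construction. Signal over background left 3347 of 30656 bovine sequences untested, and an array had 73.3% to 79.1% of them above the threshold.

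With both species normalised together, 14000 sequences differed between the lines without LPS and 13748 at 4 h, and 3 parasite sequences changed at 4 h. With the authors' values these were 14026, 13752 and 1. The parasite RNA on TBL20 arrays could account for the lower bovine values under both settings, in which 17.8% and 17.4% of the sequences called without LPS were higher in TBL20 and the median of all sequences was -0.25 and -0.43, but this was not tested. Median scaling gave 3220 for BL20 at 4 h and 3924 at 18 h, 276 and 2619 for TBL20, 1711 for the interaction at 4 h, 3395 and 997 for 18 h against 4 h in BL20 and TBL20, 2 for the parasite at 4 h, and a correlation of the LPS response between lines of 0.120. It moved the median of all sequences by over 0.1 for the lines without LPS (0.16), TBL20 at 18 h (-0.13) and the interaction at 18 h (-0.17).

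For TBL20 at 4 h, TBL20 at 18 h and TBL20 at 18 h against 4 h, fits to the groups compared gave 2157, 472 and 804, copy 1 of the probes 725, 549 and 991, and copy 2 566, 383 and 669. Copy 2 also gave 5237 for BL20 at 18 h and 2140 for the interaction at 18 h. For TBL20 at 18 h the mean of probes gave 1317, scan batch as a block 284, the first scan batch alone 407 and leaving out the 4 arrays of high background 463. For TBL20 at 18 h against 4 h the first batch alone gave 748 and the second 163, and array weights gave 3054 for TBL20 at 4 h. For the parasite, scan batch as a block gave 5 at 4 h and 135 at 18 h, the first batch alone 781 at 18 h, the replicate block 6 at 4 h and leaving out the 2 TBL20 arrays of high background 9. The replicate block gave 7939 for BL20 at 18 h and 6691 for BL20 at 18 h against 4 h. In these 2 comparisons every same-number correlation exceeded 0.1. The block was 1 factor over all 18 arrays, so these counts do not test a pairing within the 2 comparisons alone. The correlation of infection with LPS was -0.158 with no shared array, but the infection contrast used there holds minus the 4 h response of BL20, which correlated at 0.677 with its 18 h response, so this sign says nothing about infection without LPS.

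A change of at least 2-fold left 1994, 1998 and 2199 for the lines without LPS, at 4 h and at 18 h, 1145 and 1026 for BL20 at 4 h and 18 h, 72 and 123 for TBL20, 1198 and 943 for the interaction, and 710 and 118 for 18 h against 4 h in BL20 and TBL20. An adjusted p under 0.01 left 4774 for BL20 at 18 h, 516 and 341 for TBL20, 2439 and 1869 for the interaction, and 4082 and 619 for 18 h against 4 h. Of the lists camera with an estimated correlation called 39 and fry 189, against 97.

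With each array left out in turn, counts ranged from 7644 to 7999 for the lines without LPS, 7741 to 8687 at 4 h and 8497 to 10253 at 18 h. For BL20 they were 4793 to 5252 at 4 h and 5709 to 7547 at 18 h, for the interaction 3146 to 3623 and 2669 to 3546, and for BL20 at 18 h against 4 h 4981 to 6767. For TBL20 at 4 h they were 666 (without control 3) to 905 (without control 1), at 18 h 415 (without control 3) to 747 (without LPS 18 h 2), and at 18 h against 4 h 701 (without LPS 4 h 1) to 1578 (without LPS 18 h 3). Parasite counts were 2 (without control 2) to 7 (without LPS 4 h 1) at 4 h, and 151 (without control 2) to 608 (without LPS 18 h 3) at 18 h. Lists called were 92 to 99, the correlation of infection with LPS 0.259 to 0.302 and that between lines 0.198 to 0.288. An arm of 2 arrays was assumed to vary like the other groups, and so was the lone TBL20 array at 18 h in the first scan batch and at 4 h in the second, whose counts say little about a batch effect.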

Other observations

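The genes and sets in this part were chosen after their values were seen. Some genes changed more after LPS in TBL20 than in BL20. In all, 542 sequences at 4 h (317 of them higher) and 233 at 18 h (134 higher) changed in TBL20 with a called interaction of the same sign. These counts include sequences that went the opposite way in BL20, by a smaller or a larger amount. They are thus not counts of larger responses in TBL20. At 18 h the interaction was 2.03 for PLAU, 1.74 for ALDH1A1, 1.60 for CCL22, 1.58 for IL1RN and 1.48 for IL1R2, and at 4 h it was 1.74 for IL1R2 and 1.64 for PRSS54. IL1R2 and IL1RN encode proteins that block interleukin 1. In BL20, IL1RN and at 18 h CCL22 were above background on no array and IL1R2 on at most 2 of a group, so their changes there do not measure a response. At 4 h CCL22 was above background on all 3 BL20 arrays, with a mean level of 7.77 in BL20 and 8.62 in TBL20. Its response at 4 h did not pass the interaction test. Its fitted changes were 1.05 in BL20, from a control at background, and 0.93 in TBL20 (interaction -0.12, limma adjusted p = 0.82).

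Sequences that changed the same way in both lines numbered 265 up and 190 down at 4 h and 367 up and 100 down at 18 h. Reported as BL20 and TBL20 log2 changes, at 4 h CYBB, a subunit of the phagocyte oxidase, rose by 1.09 and 0.95, DHRS9 by 1.58 and 1.13 and GADD45B by 0.98 and 0.81, while LCK had a change of -1.60 in BL20 and fell to the background threshold in TBL20. At 18 h CYBB rose by 1.25 and 1.08 and IL2RA by 3.20 and 0.85, while ALOX5AP had -0.90 and -0.93 and CD3G -0.73 and -0.78. The interaction was past the test for IL2RA at 18 h.

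Of 122 sequences at least 2-fold higher at 18 h in TBL20, 107 were predicted transcripts (87.7%, against 53.3% of all tested) and 13 had a gene symbol. In BL20 84 of the 122 were also called higher at 18 h. Their median change at 18 h was 1.56 in TBL20 and 1.72 in BL20, against 0.59 and 0.26 at 4 h, and 1.57 in TBL20 within the first scan batch, which holds 1 array at 18 h. The interaction was not past the test for 81 of them.

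The cholesterol genes at 4 h had medians of -1.15, -1.06 and -1.04 on the 3 TBL20 arrays, the array of the second scan batch among them.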
